A study of Mus musculus with 3 samples.

How the data were processed

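The deposited files hold whole-number UMI counts per gene and cell barcode, 1 filtered matrix for each of the 3 libraries, over the same 31053 gene identifiers. The authors made these counts with Cell Ranger, of which versions 3.0.0 and 3.0.1 are named. The genome build and annotation are not given in the sources used here. No normalised values were used, and everything described next started from the counts. The computation ran in Python 3.11.15 with scanpy 1.11.5 and in R 4.3.3 with edgeR 4.0.16, with fixed seeds.

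Barcodes with at least 200 detected genes and at most 10% mitochondrial UMIs were kept. In each library the cells with the highest Scrublet doublet scores were then removed, 0.8% of them per 1000 barcodes, which took 1146 naive, 2 non-primed and 53 primed cells. Cells were clustered over the 3 libraries together, without batch integration. Each cell was thinned to 1000 UMIs for this step, mitochondrial, haemoglobin and ribosomal protein genes were left out, and the 2000 most variable genes gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 0.6. A cluster took the class whose marker list had the highest mean log2 fold over the other clusters, above 0, with at least 3 markers 1.5-fold up and at a CPM of at least 50. The name was kept only where the 10 genes that most set the cluster apart from clusters of other classes held no more markers of another class than of its own. Pericyte and smooth muscle lists were joined as mural, and lining and sublining lists as fibroblast. The marker lists were fixed before the data were examined, as were the gene lists, the filters and the first set of alternatives. The exact thresholds of the naming rule were set after the clusters had been seen. Classes are called fibroblast-like and so on because the names rest on transcripts alone.

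UMIs were summed over the cells of a class in each library and divided by the sum of non-mitochondrial UMIs to give CPM. A gene was measured when its mean CPM over the 3 libraries was at least 20 in fibroblast-like cells, which 5268 genes were. Log2 ratios had 0.5 UMIs added to both counts, while printed ratios had none added. Intervals of ratios are exact conditional binomial limits at 95%. Where a library had 0 UMIs, the ratio is given as a bound against 3 UMIs in that library. With 1 library per group there was no estimate of the spread between animals, so no test between groups was made. For the same reason counts of genes at least 2-fold apart, planned at first, are not given. The intervals and the random lists were checked on simulated Poisson counts only. This is the model that the intervals assume, so spread between cells was not covered.

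The 23 gene lists were complement components, complement receptors and regulators, inflammasome and pyroptosis, HIF1 targets, glycolysis, oxidative phosphorylation (nuclear), mTORC1 and lysosome, inflammatory cytokines and chemokines, NF-kappaB feedback, interferon response, antigen presentation, matrix proteases and inhibitors, collagens and matrix, bone remodelling signals, myofibroblast, synovial lining, sublining, dissociation and immediate early, heat shock, hypoxia-independent stress and p53, senescence, cell cycle, and ribosomal proteins. The symbol rule for ribosomal proteins also takes genes of S6 kinases. For each list with at least 3 measured members the median log2 ratio was compared with 10000 random lists of the same size whose members came from the same 20 bins of mean CPM, and its range under counting error came from 1000 Poisson draws. A member was called higher or lower at a ratio of at least 1.5. These percentiles describe the libraries and not the conditions.

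Named genes were chosen by a rule fixed beforehand. In each comparison these were the 10 highest and 10 lowest measured genes by the bound of the counting interval nearest to 0, up to 4 members of each gene list with the largest log2 ratio, and 15 genes whatever their values. Some of the genes that this rule takes are not reported here. The ranking left out mitochondrial and ribosomal protein genes, gene models named Gm with digits or ending in Rik, genes of the sex chromosomes that mark sex, and marker genes of blood and immune cells, skeletal muscle and keratinocytes. Shares of cells with a UMI were taken after thinning each cell to 500 UMIs. Classes other than the fibroblast-like one and single clusters were compared where both libraries held at least 50 cells.

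The alternatives changed 1 choice at a time. They covered the filters, the doublets, the resolution, clustering of each library alone, the scaling, the weighting of cells, the depth per cell, the measured genes and the clusters that entered the sums. For the same make-up, clusters 1, 5 and 9, the ones with at least 5 cells in each library, had the same weights in every library, and clusters 0 and 2 were left out. TMM factors came from edgeR on the class sums, and median-of-ratios size factors from 10945 genes with UMIs in all 3 libraries.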

Results

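Cells lacking the surface proteins CD45 and CD3, which mark leukocytes and T cells, were sorted from collagenase-digested paws of BALB/c mice. Droplet-based single-cell RNA sequencing counted unique molecular identifiers (UMIs), one for each captured transcript, per gene and cell barcode. Monosodium urate (MSU), the crystal that forms in gouty joints, was injected into paws of 2 groups. The primed library came from a paw injected at days 0 and 9, the non-primed library from a paw injected at day 9 alone, and the naive library from an uninjected paw. Cells of all 3 were taken at day 18, 9 days after the last injection. The labels give 1 library per group and not how many mice each library holds, so no difference below has a replicate check, no test was run, and every statement compares these 3 libraries rather than the conditions.

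The naive library held 13237 barcodes with 12867949 UMIs in total and a median of 814 per barcode. The non-primed library held 981 barcodes with 4803610 UMIs and a median of 3646. In the primed library there were 3471 barcodes, 3971552 UMIs and a median of 741. Filters on detected genes, mitochondrial share and doublet score left 9678 naive, 190 non-primed and 1851 primed cells, with median depths of 781, 5069 and 746 UMIs. The non-primed values therefore rest on few, deeply sequenced cells. UMI levels below are counts per 1000000 non-mitochondrial UMIs (CPM) summed over all cells of a class in a library. Ratios carry a 95% interval in brackets from exact conditional counting limits, CPM values have exact Poisson limits, and shares have exact Clopper-Pearson limits, while a count of 0 is given with the share that 3 counts would make. All these cover counting error only.

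Fibroblast-like cells were the largest class in the naive and primed libraries, and vessel-associated cells took a larger part of both injected libraries than of the naive one. Fibroblast-like cells made up 47.4% (46.4 to 48.4) of 9678 naive cells, 23.7% (17.8 to 30.4) of 190 non-primed cells and 33.8% (31.7 to 36.0) of 1851 primed cells. Blood endothelial-like cells made up 3.02% (2.69 to 3.38), 8.42% (4.89 to 13.3) and 15.7% (14.0 to 17.4) in the same order. Mural-like cells, the pericytes and smooth muscle cells around vessels, made up 0.548% (0.410 to 0.716), 26.8% (20.7 to 33.7) and 11.4% (9.99 to 12.9). Lymphatic endothelial-like cells were 0.0620% of the naive, 1.05% of the non-primed and 7.73% of the primed cells. Skeletal muscle-like cells made up 21.4% (20.6 to 22.2) of the naive, 22.6% (16.9 to 29.2) of the non-primed and 1.51% (1.01 to 2.18) of the primed cells. Without them the fibroblast-like shares were 60.3%, 30.6% and 34.3%. Tenocyte-like cells made up 15.9%, 10.5% and 10.7%, satellite cell-like cells, the muscle stem cells, 6.57%, 2.63% and 6.92%, and Schwann-like cells 1.47%, 2.63% and 1.40%. Osteoblast-like cells were 2.25% of the naive and 4.16% of the primed cells. They were 0 of the 190 non-primed cells, where 3 cells would make 1.58%. Leukocyte-like cells, which the sort should remove, made up 0.0310%, 1.58% and 5.02%, and 1.34% of naive and 1.67% of primed cells stayed unnamed. With at most 20% mitochondrial UMIs, 48.6% of the non-primed cells were leukocyte-like, and over the alternatives the non-primed share lay between 3.44% and 33.2% for blood endothelial-like and between 11.7% and 34.7% for mural-like cells, so no order of the injected libraries was read for these classes. The leukocyte-like cluster with at most 20% mitochondrial UMIs, 212 of its 320 cells being non-primed, had a median of 52.8% haemoglobin UMIs. The sort, the dissection and the number of cells loaded can each set these shares.

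**Figure D1:**
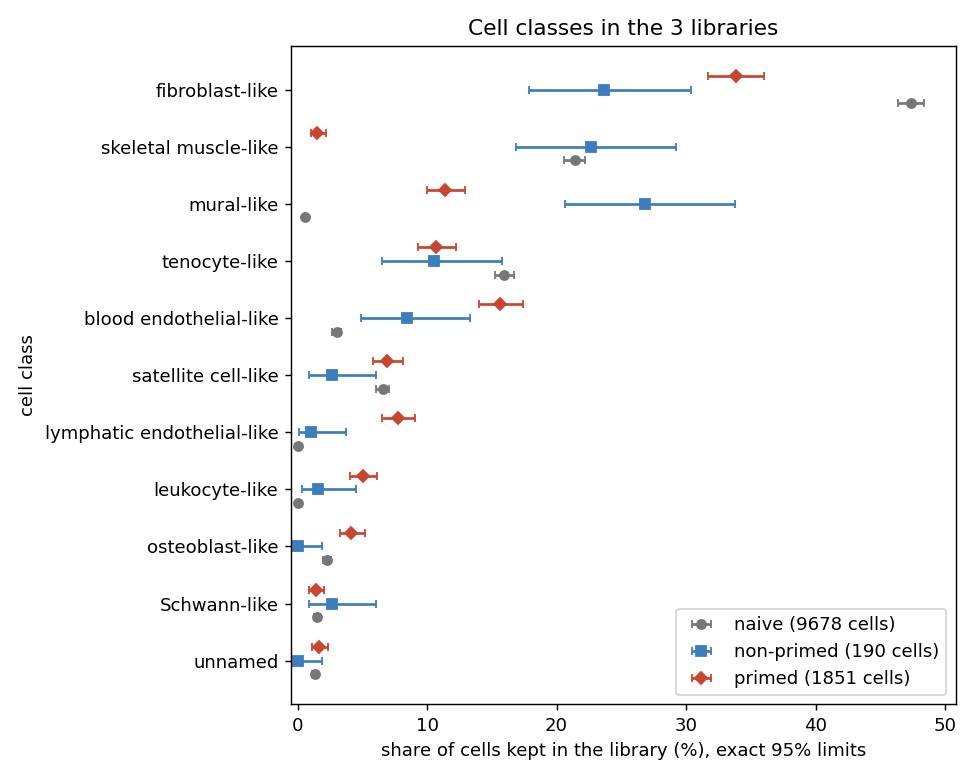
Share of cells in each class (x axis, percent of cells kept in a library) in the naive, non-primed and primed libraries, with exact 95% binomial limits as error bars. Mural-like cells lie at 0.548% in the naive, 26.8% in the non-primed and 11.4% in the primed library.

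The fibroblast-like class joined 5 clusters, numbered 0, 1, 2, 5 and 9, and different clusters held most of it in different libraries. Cluster 1 held 55.1% of the naive and 60.0% of the non-primed fibroblast-like cells. Cluster 2 held 45.4% of the primed fibroblast-like cells, cluster 1 another 28.3%, and cluster 9 held 29.5% of the naive ones. Cluster 5, named by markers of the synovial lining, held 11.8%, 13.3% and 16.0% of the naive, non-primed and primed fibroblast-like cells. As 284 of the 319 cells of cluster 2 were primed, this cluster may be that library rather than a cell type, and values within the whole class mix these clusters. Mmp3, C3, Cxcl5 and Cfb are among the 10 genes that set cluster 2 apart. Its name was kept on a tie, with 1 fibroblast and 1 leukocyte marker among these 10. Under several alternatives, clusters set apart by Mmp3 and Cxcl5 stayed unnamed. They held 220 primed cells without immediate early and heat shock genes, 105 with at most 20% mitochondrial UMIs and 128 at resolution 1.2. The primed fibroblast-like share was then 21.2%, 23.8% and 18.6%. Markers of other cell types in the fibroblast-like cells also differed between the libraries: skeletal muscle markers summed to 5803, 256 and 666 CPM in the naive, non-primed and primed library, haemoglobin and other erythroid markers to 211560, 35651 and 148660, tenocyte markers to 1545, 3402 and 3761, adipocyte markers to 681, 365 and 136, pan-leukocyte markers to 0.935, 6.68 and 1.62 and neutrophil markers to 13.3, 20.04 and 695. Of the 429 primed UMIs of neutrophil markers 426 came from Lcn2 (lipocalin 2), singled out after its values were seen, while S100a8 and S100a9 had 1 and 2. Over the 5268 measured genes, the median log2 ratio was -0.17 for primed over non-primed, 0.35 for non-primed over naive and 0.18 for primed over naive. With TMM factors these medians were -0.02, -0.08 and -0.10, so each list median below was read against the median of all genes and with its percentile among 10000 random gene lists of the same size and expression.

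The comparison of primed with non-primed fibroblast-like cells sets a paw injected on both days against one injected on the later day alone. In the primed library Saa3, Mmp3, Cxcl2 and Cxcl5 stood far above the non-primed library, while 6 of 9 complement components and 7 of 10 markers of the sublining, the connective tissue layer under the synovial surface, stood lower. Saa3, an acute-phase serum amyloid, reached 4216 CPM against 28.9, a ratio of 146 (85.0 to 274). Mmp3 (stromelysin), which cleaves cartilage matrix, had 5099.9 against 588 CPM, a ratio of 8.68 (7.65 to 9.87). C3, the central complement component, was lower in the primed library, with 1143 against 2692 CPM, a ratio of 0.425 (0.387 to 0.466).

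By the fixed ranking, the genes highest in the primed over the non-primed library were Saa3, the collagenase Mmp13 (298 CPM against 0 UMIs, at least 44.6-fold higher), the neutrophil chemokines Cxcl2 (400.03 against 4.45 CPM, ratio 89.8 (24.6 to 746) from 2 non-primed UMIs) and Cxcl5 (1317 against 53.4, ratio 24.6 (16.4 to 38.7)), the matrix glycoprotein Thbs4 (1752 against 102, ratio 17.1 (12.7 to 23.5)), the adhesion molecule Chl1 (ratio 36.0 (9.71 to 301)), Saa2 (82.6 CPM against 0 UMIs, at least 12.4-fold higher), the chemokine Ccl5 (ratio 29.1 (7.80 to 244)), Mmp3 and the chitinase-like protein Chil1 (ratio 17.7 (5.82 to 87.8)). Chl1 and Ccl5 had 2 and Chil1 had 3 non-primed UMIs. Thbs4 belongs to the tenocyte markers listed above, and the neutrophil marker Lcn2, which the ranking leaves out, had 689.9 against 13.4 CPM (ratio 51.6 (23.5 to 142)). Among the genes lowest in the primed library were the matrix protein genes Hmcn2 (16.2 against 240.5 CPM) and Mfap4 (79.4 against 479), the osteocalcin gene Bglap2 (14.6 against 125), the lipid carrier gene Apoe (400.03 against 1625), Lars2 (238 against 942), which encodes a mitochondrial tRNA synthetase, the retinoic acid-degrading enzyme gene Cyp26b1 (11.3 against 80.2), Itpkc (6.48 against 57.9), the thyroid hormone-activating enzyme gene Dio2 (17.8 against 107) and the clone-named gene model AC160336.1 (112 against 579).

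Of the 9 measured complement components, 6 were at least 1.5-fold lower and none higher in the primed library. Their median log2 ratio was -0.93 (percentile 0.03), with C1ra, a protease of the classical pathway, at 215 against 552 CPM and C1rb at 155 against 358. Receptors and regulators of complement had a median of -0.31 (percentile 29.2), with Clu higher in the primed library (ratio 7.32, but log2 0.24 with at most 20% mitochondrial UMIs). The receptors C3ar1 and C5ar1 had 0 and 1 UMIs in all fibroblast-like cells together, too few for any comparison. Sublining markers had a median of -0.97 (percentile 0.01), with 7 of 10 members lower, among them the progenitor markers Pi16 (351 against 971 CPM) and Cd34 (338 against 793). This median was -0.33 in cluster 1 alone, and clusters 1 and 9, which sublining markers name, held 60.0% and 17.8% of the non-primed but 28.3% and 3.99% of the primed fibroblast-like cells. Ribosomal protein genes had a median of -0.55, below all 10000 matched random lists, with 34 of 89 lower.

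Inflammatory cytokines and chemokines had a median of 0.56, above all 10000 matched random lists. Of their 13 measured members 6 were higher and 1 lower in the primed library, with the monocyte chemokine Ccl7 higher (863 against 183 CPM) and the eosinophil chemokine Ccl11 lower (317 against 721). Interferon response genes had a median of 0.31 (percentile 99.4), 5 of 13 being higher and 3 lower, with the interferon-induced GTPase gene Igtp higher (81.0 against 20.04 CPM, but log2 0.25 in cells with at most 5% haemoglobin UMIs) and the signal transducer Stat2 lower (16.2 against 57.9). Of 12 glycolysis genes 1 was higher, 1 lower and 10 between, with a median of 0.21 (percentile 98.9) that was -0.37 in cluster 1 alone, and Pkm, the last enzyme of the pathway, at 409.7 against 220.4 CPM. Matrix proteases and inhibitors went both ways, with Mmp3, Mmp13 and the inhibitor Timp1 higher (Timp1 1254 against 191 CPM) and the aggrecanase Adamts4 lower (22.7 against 102, but log2 1.70 in cluster 1 alone), around a median of -0.25 (percentile 48.2). Values in cluster 1 alone rest on 27 non-primed cells, and that of Adamts4 on few UMIs, so no reversal was read for it. The NF-kappaB feedback median was -0.30 (percentile 26.5), with the inhibitor gene Tnfaip3 at 19.4 against 95.7 CPM (log2 -0.35 in thinned cells). Collagens and matrix genes had a median of 0.01 (percentile 98.4), with Tnc higher (100.4 against 6.68 CPM) and the elastin gene Eln lower (30.8 against 156, log2 -0.36 with at most 5% mitochondrial UMIs). The 4 measured inflammasome genes had a median of -0.75 (percentile 2.59) in all cells and 0.23 in cells with at most 5% haemoglobin UMIs. For antigen presentation the median was -0.09 (percentile 75.1), and under TMM factors, median-of-ratios size factors and totals without ribosomal and haemoglobin genes it was above 0.

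Of single genes fixed beforehand, Hif1a, the hypoxia-induced transcription factor, had 194 against 169 CPM, a ratio of 1.15 (0.855 to 1.55), and Mtor, the growth kinase, 9.72 against 15.6 from 6 and 7 UMIs. Neither difference was detectable at this depth. Il6 had 337 against 269 CPM (ratio 1.25 (0.995 to 1.58)), also within counting error, the neutrophil chemokine Cxcl1 1719.9 against 2122 (ratio 0.811 (0.742 to 0.886)) and the monocyte chemokine Ccl2 722 against 521 (ratio 1.39 (1.18 to 1.63)). Prg4, the lubricin of the synovial lining, had a ratio of 1.32 (1.27 to 1.37), but its log2 ratio ran from -0.39 with clusters at the same make-up to 3.31 in cluster 1 alone, so no direction was read. The stromal markers Pdpn, Thy1 and Fap had ratios of 1.51 (1.14 to 2.02), 0.577 (0.414 to 0.8004) and 0.489 (0.324 to 0.731), of which the first 2 turned under other mitochondrial limits. Nlrp3, the inflammasome sensor of urate crystals, had 0 UMIs in the fibroblast-like cells of all 3 libraries. Tnfsf11 (RANKL), which drives osteoclast formation, had 7 primed, 1 non-primed and 0 naive UMIs.

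Without cluster 2, the higher level of Cxcl5, Ccl7 and Ccl2 in the primed over the non-primed cells turned, with log2 ratios of -1.34, -1.18 and -2.42, while that of Saa3 and Mmp3 stayed positive at 2.52 and 0.99. Cxcl2 was at 0.39, but so few of its UMIs remained that no direction was read. In cells with at most 5% haemoglobin UMIs Mmp3 was 0.31, and at resolution 1.2 Ccl5 turned to -0.58. Bglap2 was at 0.85 in cluster 1 alone, from too few UMIs to read a reversal. The medians of cytokines and chemokines and of the interferon response also fell below 0 without cluster 2, at -0.74 and -0.20. Lcn2 fell to 0.68, from 5.58 with it. Cluster 2 was formed by expression and is mostly primed, so leaving it out lowers genes high in it mainly in the primed library. The ratio of Ccl2 kept its sign under 12 of 18 alternatives only. The complement median was -0.56 when every cell was weighted alike and -1.93 without cluster 2. In cells thinned to 500 UMIs it was -0.52, and the median of all genes was -0.78. The 0.5 UMIs added to each count weigh most on low counts in the 45 thinned non-primed cells. That median is therefore no sound reference for complement, and no lower level was read there.

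**Figure D2:**
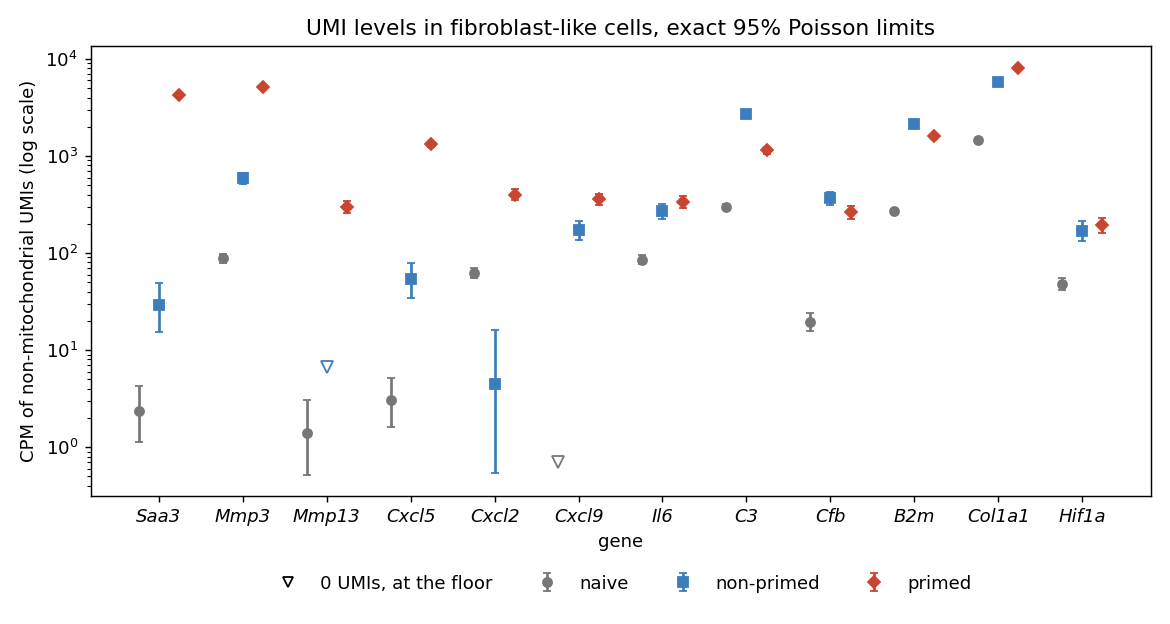
UMI level of 12 genes in fibroblast-like cells (y axis, CPM, log scale) in the naive, non-primed and primed libraries, with exact 95% Poisson limits as error bars and an open triangle at the 3-count floor where a library had 0 UMIs. C3 stands highest in the non-primed library (2692 CPM) and Mmp3 in the primed library (5099.9 CPM).

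The comparison of non-primed with naive cells shows a paw 9 days after its first crystal injection beside one that met none. Antigen presentation, complement, interferon and collagen genes all stood higher in the non-primed library, and genes of muscle fibres stood lower. All 10 measured antigen presentation genes were at least 1.5-fold higher, with a median log2 ratio of 2.58, above all 10000 matched random lists. B2m, the invariant chain of class I molecules, had 2124 against 270.2 CPM, a ratio of 7.86 (7.21 to 8.57). C3 had 2692 against 299.9 CPM, a ratio of 8.98 (8.29 to 9.72), and 8 of the 9 measured complement components were higher, with a median of 2.29, above all 10000 matched random lists.

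The interferon-induced chemokine Cxcl9 led the ranking, with 171 CPM against 0 naive UMIs, at least 245-fold higher. It was followed by the class II genes Cd74 (ratio 125 (55.1 to 352)), H2-Ab1 (ratio 30.04 (15.8 to 61.1)) and H2-Aa (ratio 40.0 (14.7 to 136)), by Plac8 (ratio 72.6 (34.6 to 176)), by Cfb, factor B of the alternative complement pathway (369.6 against 19.6 CPM, ratio 18.8 (14.4 to 24.8)), by Cyth1 (ratio 18.2 (11.9 to 28.3)), Cxcl5 (ratio 17.6 (8.61 to 37.6)), the growth factor Ptn (ratio 13.4 (11.3 to 16.0), but log2 -0.0220 with at most 5% mitochondrial UMIs) and C3. The ranked lower genes were those of muscle fibres, namely the giant sarcomere protein Ttn, with 0 non-primed UMIs (at least 27.1-fold lower, but log2 2.56 at resolution 1.2), Pgam2, also with 0 (at least 19.1-fold lower), Tcap, Car3, Myl1, Cox6a2, Mb, Eno3 and Tpm2, and Ccl21a, a chemokine of lymphatic vessels. Myl1 had 49.0 against 779 CPM and Car3 15.6 against 488. The muscle fibre genes moved with the skeletal muscle markers, which were 5803 CPM in the naive and 256 CPM in the non-primed fibroblast-like cells. Ccl21a belongs to the lymphatic endothelial markers, which were 124 CPM in the naive and 13.4 CPM in the non-primed ones.

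Interferon response genes had a median of 1.46, above all 10000 matched random lists, with 10 of 13 higher, among them the GTPase gene Iigp1 (127 against 22.2 CPM) and the viral restriction factor Bst2 (178 against 34.6). Collagens and matrix genes had a median of 1.38, above all 10000 matched random lists, with 22 of 26 higher, among them Col1a1 (5814 against 1452 CPM), Col3a1 (6787 against 1563) and Col5a1 (497 against 127). Matrix proteases and inhibitors had a median of 0.89 (percentile 99.3), with the gelatinase Mmp2 higher (ratio 3.35 (3.03 to 3.70)). Mmp3 had a ratio of 6.64 (5.65 to 7.79), but a log2 ratio of 0.61 with clusters at the same make-up and no order in thinned shares, and Adamts4 a ratio of 4.13 (2.86 to 5.90). In cluster 1 alone Adamts4 was at log2 -0.37, from too few non-primed UMIs to read a reversal. NF-kappaB feedback genes had a median of 0.84 (percentile 98.4), with Tnfaip3 (ratio 4.88 (3.30 to 7.12)) and Nfkb1 (ratio 3.72 (3.02 to 4.55)) higher. Synovial lining markers had a median of 0.72 (percentile 96.7) that turned to -0.53 in cluster 1 alone, ribosomal protein genes 0.49 (percentile 98.6) and inflammasome genes 0.96 (percentile 95.2).

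Cytokines and chemokines as a list did not stand apart, with a median of 0.16 (percentile 32.9) that was below 0 under the 3 other scalings. Il6 had 269 against 85.3 CPM (ratio 3.16 (2.55 to 3.89)), and Ccl2 521 against 529 (ratio 0.985 (0.857 to 1.13)). Hif1a had 169 against 47.9 CPM (ratio 3.53 (2.68 to 4.62)), but a log2 ratio of 0.53 with each cell thinned to 500 UMIs, where 2.29% of naive and 2.22% (1 of 45) of non-primed cells held a UMI, while the list of its targets had a median of 0.37 (percentile 54.5) that was below 0 under the 3 other scalings. Immediate early genes, which tissue digestion can induce, had a median of -0.34, below all 10000 matched random lists, with 5 of 16 lower and 1 higher and Junb at 1888 against 3428 CPM. Nuclear genes of oxidative phosphorylation had a median of -0.16 (percentile 0.01), with 4 of 30 lower, and glycolysis genes -0.05 (percentile 5.10), with Gapdh at 347 against 1362 CPM and Aldoa at 349.6 against 971. Skeletal muscle markers in these cells were lower too, at 256 against 5803 CPM, and muscle RNA was not separated from the glycolysis values. In the largest fibroblast-like cluster alone, the ratio of Il6 turned (log2 -1.58). That of Cxcl5 was -0.37 there, from too few UMIs to read a reversal.

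The comparison of primed with naive cells sets a paw injected at both days against one that met no crystals. Antigen presentation, interferon, complement and collagen genes were again higher than in the naive library, and Saa3, Mmp3, Cxcl2 and Cxcl5 reached their highest levels of the 3 libraries. All 10 measured antigen presentation genes were at least 1.5-fold higher, with a median of 3.01, above all 10000 matched random lists. Saa3 rested on 2603 primed against 10 naive UMIs, a ratio of 1804 (979 to 3766), and Mmp3 had 5099.9 against 88.6 CPM, a ratio of 57.6 (51.7 to 64.2). C3 had 1143 against 299.9 CPM, a ratio of 3.81 (3.47 to 4.18). Without cluster 2 the log2 ratios of Saa3, Mmp3 and C3 were 5.26, 1.64 and 0.42.

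The ranked higher genes were Saa3, Cxcl9 (356 CPM against 0 UMIs, at least 508-fold higher), Cxcl5 (1317 against 3.04 CPM, ratio 433 (252 to 817)), Chil1 (at least 169-fold higher), Mmp13 (ratio 212 (95.8 to 587), log2 1.23 at resolution 1.2), Mmp3, Ccl5 (ratio 92.4 (40.6 to 259), but log2 -0.97 at the same make-up, where no primed UMIs of it were left), Plac8 (ratio 55.4 (26.5 to 134)), Saa2 (ratio 58.9 (25.3 to 168), log2 0.37 in cells with at most 5% haemoglobin UMIs) and the guanylate-binding protein gene Gbp4 (ratio 46.4 (23.7 to 101.2)). The ranked lower genes were Inmt, with 0 primed UMIs (at least 17.0-fold lower), Scg3 (ratio 0.0267 (0.000672 to 0.150) from 1 primed UMI), the alcohol dehydrogenase gene Adh1 (ratio 0.0303 (0.000763 to 0.170) from 1), the co-stimulatory ligand gene Tnfsf9 (11.3 against 179.7 CPM) and the muscle fibre genes Tcap, Car3, Ttn, Pgam2, Cox6a2 and Myl1. The latter moved with the skeletal muscle markers, at 666 CPM in the primed and 5803 CPM in the naive fibroblast-like cells. Neutrophil markers, nearly all of them Lcn2 UMIs, moved with the ranked higher genes, at 695 against 13.3 CPM. The log2 ratio of Cxcl5, 8.71 here, fell to 2.76 at the lowest over 18 alternatives.

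Complement components had a median of 1.41 (percentile 99.99), with 8 of 9 higher, among them Cfb (264 against 19.6 CPM) and C2 (71.3 against 19.2). Over 18 alternatives the log2 ratio of Cfb lay between 0.67 and 3.86 and that of C2 between 1.10 and 2.27. Interferon response genes had a median of 1.07, above all 10000 matched random lists, with 1 of 13 lower and 9 higher, among them Iigp1 (ratio 15.8 (12.4 to 20.4)), Igtp (ratio 15.1 (9.02 to 25.9)) and Bst2 (ratio 9.55 (7.69 to 11.9)). Collagens and matrix genes had a median of 1.23, above all 10000 matched random lists, with 17 of 26 higher, among them Col1a1 (ratio 5.62 (5.41 to 5.83)), Col3a1 (ratio 4.83 (4.66 to 5.02)) and the injury-related matrix gene Tnc (ratio 13.0 (8.40 to 20.5)). Matrix proteases and inhibitors had a median of 0.70 (percentile 99.7), with Timp1 at a ratio of 6.43 (5.82 to 7.10). Synovial lining markers had a median of 0.69 (percentile 99.5), with Prg4 (ratio 1.62 (1.58 to 1.66)) higher and the hyaluronan synthase gene Has1 (ratio 0.239 (0.193 to 0.293)) lower, and sublining markers -0.37 (percentile 2.06). Hif1a had 194 against 47.9 CPM, a ratio of 4.06 (3.21 to 5.11), and a log2 ratio of 0.97 in cells with at most 5% haemoglobin UMIs.

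Inflammatory cytokines and chemokines had a median of 1.15, above all 10000 matched random lists, 7 of 13 being higher and 1 lower, with Il6 (ratio 3.95 (3.31 to 4.69)), Cxcl2 (ratio 6.39 (5.35 to 7.62)) and Cxcl10 (ratio 5.03 (3.90 to 6.46), log2 0.0969 in cells with at most 5% haemoglobin UMIs) higher and Cxcl1 at 1719.9 against 1909 CPM. This direction rested on cluster 2: without it the list median was -0.48, the log2 ratio of Il6 was -1.99 and that of Cxcl2 -2.93. Cluster 2 was formed by expression and held 284 of 626 primed but 32 of 4585 naive fibroblast-like cells. Leaving it out therefore lowers genes high in it mainly in the primed library. Antigen presentation kept a median of 2.24 without cluster 2, while that of complement fell to 0.48, and in cluster 1 alone it was 0.55 with 4 of 9 members higher. Immediate early genes had a median of -0.59 (percentile 0.05), with 8 of 16 lower and none higher, and nuclear genes of oxidative phosphorylation one of -0.29 (percentile 0.230), with 3 of 30 lower and 27 between. The medians of the other fixed lists were 0.05 for HIF1 targets (below 0 under the 3 other scalings), -0.02 for glycolysis, 0.25 for mTORC1 and lysosome genes, 0.26 for NF-kappaB feedback (both below 0 with TMM factors, the latter -0.95 without cluster 2), -0.02 for heat shock, 0.30 for hypoxia-independent stress and p53 genes, 0.55 for senescence, 0.51 for cell cycle, -0.16 for myofibroblast markers (1.18 in cluster 1 alone), 0.62 for bone remodelling signals (below 0 under 5 alternatives, at the lowest -0.26), 0.74 for inflammasome and pyroptosis genes, -0.08 for complement receptors and regulators and -0.03 for ribosomal proteins, all between percentiles 21.9 and 96.6.

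**Figure D3:**
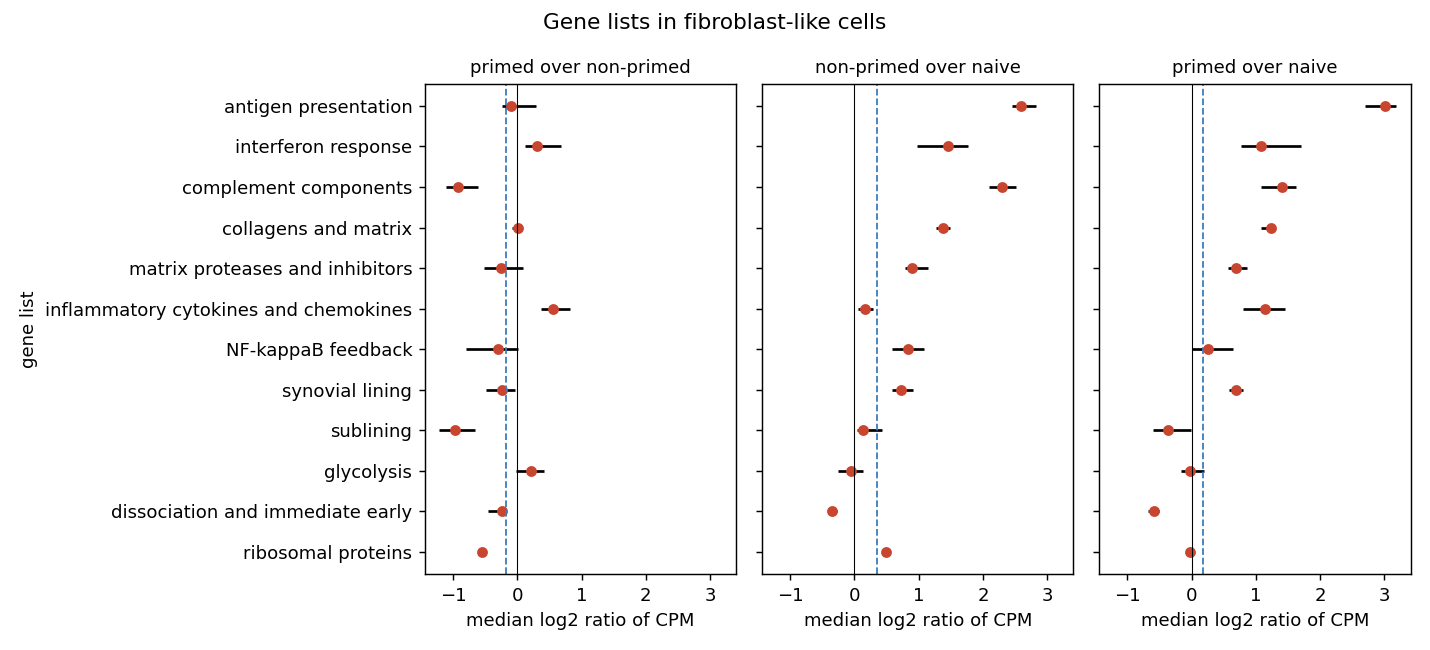
Median log2 ratio (x axis) of 12 of the fixed gene lists in fibroblast-like cells for primed over non-primed, non-primed over naive and primed over naive, with bars for the 95% range of counting error and dashed lines at the median of all measured genes. Antigen presentation lies at 2.58 and 3.01 in the comparisons with the naive library and at -0.09 between the injected libraries, where it is above 0 under the 3 other scalings.

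Shares of fibroblast-like cells with a UMI, after thinning every cell to 500 UMIs, gave the same order as CPM for C3, although the intervals of both injected libraries overlap. For C3 the share was 11.1% (10.2 to 12.0) in the naive, 37.8% (23.8 to 53.5) in the non-primed and 28.0% (24.5 to 31.6) in the primed library, against 16.7%, 60.0% and 38.5% without thinning. In blood endothelial-like cells it was 6.51%, 0 of 16 cells, too few for a level to compare, and 3.45%. For Mmp3 the thinned shares were 3.49%, 2.22% and 32.4%, against 5.30%, 28.9% and 40.3% without thinning. In blood endothelial-like cells they were 3.42%, 0 of 16 cells and 1.38%. The primed share thus stood above that of blood endothelial-like cells, and no order was read between the naive and non-primed libraries. Median depths were 788, 6647 and 763 UMIs in fibroblast-like and 967, 13154 and 785.5 in blood endothelial-like cells. All cells held at least 500 UMIs, so none was left out.

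Antigen presentation genes were also higher in the primed than in the naive library in the 5 other classes with at least 50 cells in both, and so was the interferon response, while cytokines and chemokines were higher in blood endothelial-like, mural-like and osteoblast-like cells and lower in satellite cell-like and tenocyte-like cells. In blood endothelial-like cells the median log2 ratio was 2.82 for antigen presentation, 2.81 for the interferon response and 3.24 for cytokines and chemokines, each above all 10000 matched random lists. The interferon-induced chemokine Cxcl10 had 3307 primed against 15.2 naive CPM, Cxcl9 2496 against 3.03 and Il6 995 against 33.4. Vcam1, an adhesion molecule for leukocytes, had 623 against 72.8 CPM, and all 13 measured NF-kappaB feedback genes were higher, with a median of 1.64. Mural-like cells had at least 50 cells in all 3 libraries. Their antigen presentation median was 3.95 for non-primed over naive, 3.87 for primed over naive and 0.08 for primed over non-primed. For 4 of the 8 members the naive library had 0 UMIs, and with these at their bound the medians over naive were 2.01 and 2.18. The mural chemokine median was 1.06 for primed over non-primed, with Cxcl10 at 2504 against 525 CPM and Cxcl1 at 4499 against 1205. Antigen presentation medians for primed over naive were 3.34 in osteoblast-like, 2.89 in satellite cell-like and 1.83 in tenocyte-like cells. Of the 77 primed osteoblast-like cells 49 lay in cluster 19, which held no naive cells, so the osteoblast-like medians compare different clusters. Those of the interferon response were 1.56 in mural-like (1.08 with genes at 0 UMIs at their bound), 4.27 in osteoblast-like (2.69 at the bound), 2.01 in satellite cell-like and 1.70 in tenocyte-like cells. Those of cytokines and chemokines were 2.86 (1.73 at the bound), 3.54, -2.20 and -0.86 in the same order, with 8 of 12, 9 of 9, 1 of 7 and 3 of 11 members higher and 2, 0, 6 and 6 lower. In satellite cell-like cells immediate early genes were lower as well, with a median of -1.02, and median haemoglobin was 31.7% of UMIs in the primed against 14.8% in the naive library. Immediate early genes were also lower in blood endothelial-like cells, where chemokines were higher, with a median of -0.97 and 10 of 15 lower. Within the fibroblast-like class the antigen presentation medians were 3.15 in cluster 1 and 1.42 in the lining cluster 5.

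**Figure D4:**
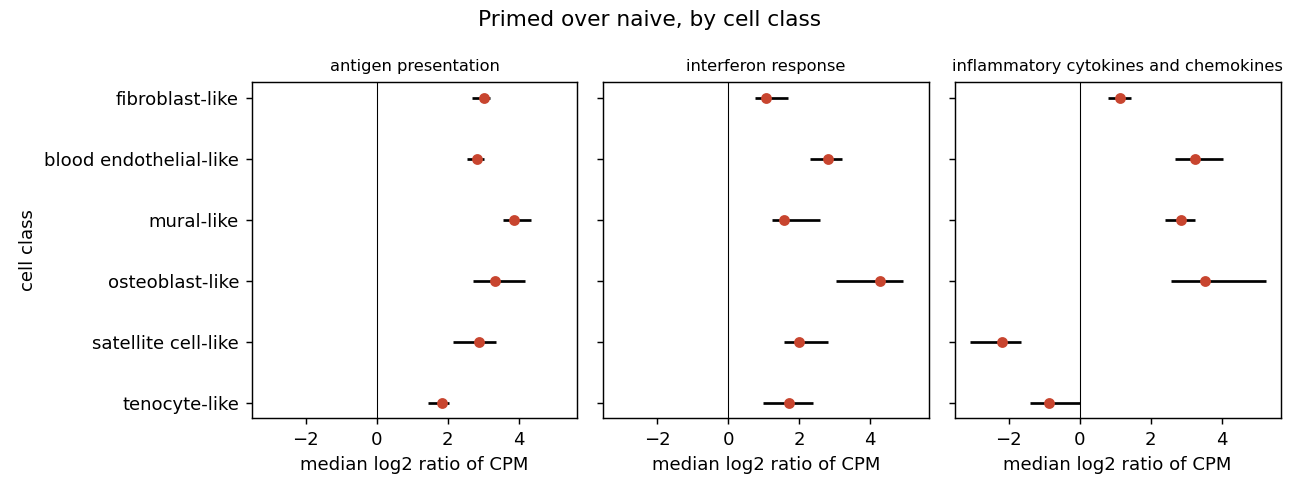
Median log2 ratio of primed over naive (x axis) for antigen presentation, interferon response and inflammatory cytokine and chemokine genes in each class with at least 50 cells in both libraries, with bars for the 95% range of counting error. Cytokines and chemokines lie at 3.24 in blood endothelial-like and -2.20 in satellite cell-like cells. Most primed osteoblast-like cells belong to a cluster with no naive cells.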

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

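The tests below were chosen after the results were seen, except those on RNA from blood endothelial cells and on the number of libraries.

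In blood endothelial-like cells the synovial lining list had a median log2 ratio of -0.75 for primed over naive, against 0.69 in fibroblast-like cells. Inflammatory cytokines and chemokines had medians of -2.20 in satellite cell-like and -0.86 in tenocyte-like cells, against 1.15 in fibroblast-like cells. They stood out because the class values went opposite ways in the same pair of libraries, and the difference was not tested. Sublining markers were lower still in blood endothelial-like cells, with a median of -2.98 (percentile 0) and 4 of 6 members lower. The lower lining value there was thus not particular to the lining list. The fibroblast-like chemokine value rests on cluster 2: without it the median was -0.48, in cluster 1 alone -0.33 and at the same make-up, which leaves cluster 2 out, -0.86, the direction of the satellite cell-like and tenocyte-like cells. Cluster 2 was formed by expression and is mostly primed, so leaving it out lowers genes high in it mainly in the primed library. Over all barcodes, those outside the comparisons included, signals of other origin also stood out. Haemoglobin genes gave most UMIs in 65.7% of the non-primed barcodes, against 13.0% of the naive ones. Mitochondrial genes did so in 7.95% of the non-primed and 18.6% of the primed barcodes, against 1.16% of the naive ones.

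Antigen presentation genes were higher in the primed than in the naive fibroblast-like cells. The values argue against RNA or doublets from leukocytes, which the CD45 sort should remove, as the cause for the class I genes. Pan-leukocyte markers had 1 UMI in 626 primed fibroblast-like cells, 1.62 CPM against 2052 in leukocyte-like cells. At the upper counting limit of the markers this carries 0.592% of the class I excess of the primed over the naive cells, with 7043 against 1522 CPM. For the class II genes H2-Aa, H2-Ab1 and Cd74 the upper limit is 43.8% of an excess from 5.61 to 149 CPM, so leukocyte RNA and expression in the fibroblast-like cells cannot be told apart with so few marker UMIs. RNA from blood endothelial cells carries at most 4.32% of the class I excess, from 31 marker UMIs. With 1 library per group, a difference between single libraries other than the injections stays open. The biological explanation that injected paws hold fibroblasts with more antigen presentation transcripts may also hold but was not tested.

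Complement components were lower in the primed than in the non-primed fibroblast-like cells. The values argue against more free red cell RNA in the primed cells as the cause, since in cells with at most 5% haemoglobin UMIs, 46 primed and 34 non-primed, the median stayed at -0.88. Whether other shares of the clusters account for it could not be decided. With clusters 1, 5 and 9 at the same make-up and cluster 2 left out the median was -1.47, although 6 and 8 non-primed cells lie behind clusters 5 and 9. In cluster 1 alone, with 27 non-primed cells, it was -1.73. But cluster 2 was formed by expression, is mostly primed and is set apart by C3 and Cfb among others. Leaving it out therefore lowers complement mainly in the primed library. A few deep non-primed cells stay open: without the deepest cell of each library the median was -1.16, but with every cell weighted alike it was -0.56, inside the limit of 0.58 that had been set. In cells thinned to 500 UMIs the complement median was -0.52, also inside that limit, so no lower level was read there. The median of all genes there, -0.78, is no sound reference for it. The 0.5 UMIs added to each count weigh most on low counts in the few thinned non-primed cells. A lower complement level after repeated injection remains an open hypothesis beside the difference between 2 single libraries.

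The 10 genes ranked higher in the primed than in the non-primed library were set against free RNA and doublets. Free RNA spread over all primed cells keeps genes in 1 ratio to haemoglobin in every cell type. Relative to haemoglobin, the median log2 difference of the 10 genes between primed fibroblast-like and blood endothelial-like cells was 4.65 (4.03 to 5.40 by counting), which argues against free RNA for the genes as a set, although Cxcl2 was alike in both, at 0.08. In cluster 2, pan-leukocyte markers reached at most 0.854% of their level in leukocyte-like cells, which argues against doublets with leukocytes. Neutrophil markers were 695 CPM in primed against 20.04 in non-primed fibroblast-like cells, but 426 of their 429 primed UMIs came from Lcn2: in cluster 2 Lcn2 reached 41.9% of its level in leukocyte-like cells and S100a9 0.553% of its own. Cells between fibroblast and tenocyte or osteoblast in the primed paw stay open and were not tested.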

How the results depend on the processing

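Most alternatives were chosen before the data were examined, while those without the deepest cell of each library, without cluster 2, with at most 5% haemoglobin, with genes measured in the 2 libraries compared and without skeletal muscle-like cells were chosen after the results were seen. No paired analysis was possible because each group had 1 library. Where a value moved and no cause is named, the cause was not tested.

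Over 18 alternatives the antigen presentation median lay between 2.17 and 3.01 for non-primed over naive and between 2.24 and 3.15 for primed over naive, and the complement median between 1.88 and 2.39 and between 0.48 and 1.64. For primed over non-primed, complement lay between -1.93 and -0.52, while antigen presentation, from -0.43 to 0.44, had no direction. The value of -0.52 came from cells thinned to 500 UMIs, where no lower level was read. Fibroblast-like shares were higher in the naive than in the primed library under every alternative with shares.

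Scaling moved the median of all genes. For primed over non-primed, non-primed over naive and primed over naive it was -0.17, 0.35 and 0.18 with CPM, -0.02, -0.08 and -0.10 with TMM factors and 0.02, -0.07 and -0.05 with median-of-ratios factors. Among genes at least 2-fold apart, 88.2% were higher in the non-primed than in the naive library with CPM and 52.0% with TMM factors, so the general excess of higher genes there follows the scaling. For non-primed over naive, antigen presentation was 2.17 with TMM factors, 2.18 with median-of-ratios factors and 2.33 without ribosomal and haemoglobin genes, and complement 1.88, 1.89 and 2.04.

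Filters and clustering moved other values. With at least 400 genes per cell, complement was -1.40 and antigen presentation -0.26 for primed over non-primed, antigen presentation 2.45 for non-primed over naive and 2.48 for primed over naive, the fibroblast-like shares 48.4% in the naive and 28.7% in the primed library, and Il6 turned to -0.58 for primed over naive. With at most 20% mitochondrial UMIs, antigen presentation was 0.44 for primed over non-primed and 2.34 for non-primed over naive, the fibroblast-like shares were 45.9%, 16.7% and 23.8%, 48.6% of the non-primed cells were leukocyte-like, 11.7% mural-like, 9.40% skeletal muscle-like and 3.44% blood endothelial-like, and Thy1 turned to 0.033 for primed over non-primed. The leukocyte-like cluster there had a median of 52.8% haemoglobin UMIs. With at most 5% mitochondrial UMIs, Pdpn turned to -0.045 for primed over non-primed and Ptn to -0.022 for non-primed over naive. With doublets kept, complement was -1.14 for primed over non-primed and the naive share 45.0%. At resolution 1.2, complement was -1.14 for primed over non-primed, the naive and primed shares were 36.8% and 18.6%, Ccl5 turned to -0.58 for primed over non-primed and Ttn to 2.56 for non-primed over naive. Without immediate early and heat shock genes the primed share was 21.2%, and a cluster with 220 primed cells, set apart by Mmp3 and Cxcl5, stayed unnamed. Clustered alone, the libraries gave shares of 43.0%, 0% and 29.8%, so the non-primed library had no fibroblast-like cluster and this alternative gave no gene values. Its blood endothelial-like share was then 33.2%, against 14.2% in the primed library. Without skeletal muscle-like cells the non-primed mural-like share was 34.7%, and the naive and non-primed fibroblast-like shares were 60.3% and 30.6%.

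The weight of single cells and their depth mattered as well. With every cell weighted alike, complement was -0.56 for primed over non-primed and 1.96 for non-primed over naive, antigen presentation 2.36 for the latter, and bone remodelling signals turned to -0.041 for primed over naive. With each cell thinned to 500 UMIs, complement was -0.52 for primed over non-primed, 2.09 for non-primed over naive and 1.64 for primed over naive, antigen presentation -0.26 for primed over non-primed, and bone remodelling signals turned to -0.075 for primed over naive. The median of all genes in thinned cells was -0.78, 0.93 and 0.13 for primed over non-primed, non-primed over naive and primed over naive. Those with the non-primed library carry the 0.5 UMIs added to each count, which weigh most in its 45 thinned cells. They are no sound reference for complement, and no lower level was read for primed over non-primed. Without the deepest cells, complement was -1.16 and antigen presentation -0.28 for primed over non-primed. In cells with at most 5% haemoglobin, antigen presentation was 0.33 for primed over non-primed and 2.31 for non-primed over naive, and inflammasome genes turned to 0.23 for primed over non-primed.

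The clusters that entered the sums mattered most for chemokines. With clusters at the same make-up, complement was -1.47 for primed over non-primed, 1.91 for non-primed over naive and 0.79 for primed over naive, and antigen presentation -0.31 for primed over non-primed and 2.45 for primed over naive. Under it Ccl5 (-0.46), Ccl7 (-0.52) and Cxcl5 (-1.14) turned for primed over non-primed, and Ccl5 (-0.97), Cxcl2 (-2.35), Il6 (-1.75), bone remodelling signals (-0.19) and cytokines and chemokines (-0.86) for primed over naive. In cluster 1 alone, complement was -1.73, 1.98 and 0.55 for primed over non-primed, non-primed over naive and primed over naive, and antigen presentation -0.43 and 3.01 for the first 2. There Adamts4 (1.70) and Bglap2 (0.85) turned for primed over non-primed, Adamts4 (-0.37), Cxcl5 (-0.37), Il6 (-1.58) and synovial lining markers (-0.53) for non-primed over naive, and Cxcl2 (-1.79), Il6 (-0.73), bone remodelling signals (-0.26) and cytokines and chemokines (-0.33) for primed over naive. The values of cluster 1 alone rest on 27 non-primed cells. Without cluster 2, complement was -1.93, 2.07 and 0.48 and antigen presentation -0.43, 2.38 and 2.24 for the 3 comparisons in the same order. Ccl7 (-1.18) and Cxcl5 (-1.34) turned for primed over non-primed, and Cxcl2 (-2.93), Il6 (-1.99), bone remodelling signals (-0.19) and cytokines and chemokines (-0.48) for primed over naive.

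Reversals were counted for genes and lists at least 1.5-fold from 0, for genes also with a counting interval on 1 side of 0. Of the 1926 values of single genes under alternatives, 23 reversed, 627 moved beyond counting error and 1276 did not. Of the other list medians, 10 reversed, 401 moved and 720 did not. Depth limits small differences. In simulated counts with totals near those of the fibroblast-like sums, a true ratio of 4 was found at least 2-fold apart in 98.5% of genes for primed over non-primed and in 100% for the comparisons with the naive library. A true ratio of 1.5 gave the right sign in 91.7%, 93.7% and 100%. The simulation drew Poisson counts, the model that the intervals assume, so spread between cells was not simulated. In the non-primed library 11 of the 45 fibroblast-like cells held at least 50% of their UMIs, and the largest 6.21%. Detection in the real counts can therefore be poorer.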

Other observations

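In the osteoblast-like, satellite cell-like and tenocyte-like classes, genes beyond antigen presentation also differed between the naive and primed libraries, and none of these values had a test. Osteoblast-like cells of the primed library had Saa3 at 15572 against 11.6 naive CPM, Mmp13 at 8010.5 against 407, Timp1 at 4094 against 384, Col1a1 at 17450 against 4821 and Cxcl9 at 3997 against 0. Of the 77 primed osteoblast-like cells 49 lay in cluster 19, which held primed cells only and is set apart by Chil1, Mmp13, Saa3, Cxcl9 and Timp1, so these values rest in part on that cluster. The interferon response median was 4.27 for primed over naive, or 2.69 with the 4 of 13 genes that had 0 UMIs in a library at their bound.

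In satellite cell-like cells 6 of 7 cytokines and chemokines were lower and all 7 antigen presentation genes higher in the primed library, while 12 of 16 immediate early genes were lower (median -1.02) and median haemoglobin was 31.7% of UMIs against 14.8% in the naive library. Immediate early genes were also lower in blood endothelial-like cells, with a median of -0.97. In satellite cell-like cells Cxcl1 stood at 350.0 against 2458 CPM, Ccl7 at 9.72 against 233 and H2-K1 at 1488 against 127. Tenocyte-like cells had Col1a1 at 17020 against 5710.5 CPM, Cxcl10 at 204 against 11.9 and Cxcl1 at 288 against 869.

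Mural-like cells had Il6 at 48.0 CPM in the naive, 717 in the non-primed and 1659.9 in the primed library, and B2m at 216, 5211 and 2974. In blood endothelial-like cells Hif1a had 477 primed against 51.6 naive CPM, the basement membrane collagen gene Col4a1 1691 against 209 and Fos 1458 against 6602. Macrophage markers in fibroblast-like cells summed to 9.35, 15.6 and 21.1 CPM in the naive, non-primed and primed library. Cluster 18 held 31 primed cells and no others, was set apart by Ptx3, Hp, Tnfaip6, Cxcl5 and Il6, and met no marker list.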
